A study of Rattus norvegicus with 8 samples.

How the data were processed

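The series compared hippocampi of rats after intracranial self-stimulation (ICSS, 4 pools) with those of Sham rats (4 pools), each pool from 3 animals, on 8 arrays of 2 colours. Per the labels' protocols, electrodes were implanted, rats recovered for 7 days, and animals were trained or exposed to the box in sessions of 20 min before the main session. RNA, 500 ng per sample, was amplified and labelled with an Agilent low-input kit, with Cy5 for the pool and Cy3 for the common reference on every array, so no dye swap balances a dye effect, although it cancels between groups. Per the labels, the reference held hippocampal, thalamic and cortical tissue of the other side, while the design text gives hippocampal tissue of the electrode's side. The levels of the brain slices also differ between the design text and the protocol.

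The authors deposited 1 log2 ratio per feature and array, for 45220 features. Limma is named in the submitters' processing notes without a version. Background correction, normalization within and between arrays and filters are not given in the sources used here. The base of the logarithm is not stated either and was taken as log2, since limma gives log2 ratios. The direction was taken as Cy5 over Cy3 from the dyes in the labels and checked with region markers. No value was missing, array medians lay between -0.032 and 0.016, and array standard deviations between 0.360 and 0.392. No 2 arrays were identical, with a highest correlation of 0.873. Spot intensities were not used here, so no filter on dim spots was applied, and control spots could not be told apart from unnamed probes.

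Features were named through the platform annotation, whose symbols were updated through Entrez identifiers and the GRCr8 gene table, used for names only. Of the features, 25353 had 1 gene symbol, 48 had several and 19819 had none listed, and these are unnamed here. Of those with 1 symbol, 25306 matched a current gene. The unit of the tests was the gene, as the mean over its features (14870 genes, 5751 of them with 2 or more features), or the unnamed probe (19867), 34737 units in all. Features of 1 gene that disagree in sign are given with the gene or in the part on processing. Features that differ in size alone are given for some genes only. Probes of close paralogs, such as Hspa1a and Hspa1b or Mt1 and Mt2A, can pick up both.

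ICSS was compared with Sham by limma (version 3.58.1 in R 4.3.3; lmFit and eBayes, two-sided, no covariates), with Benjamini-Hochberg adjustment over all units and a threshold of 0.05. Adjusted p values are from limma unless another test is named. The prior had 3.83 degrees of freedom. Differences are ICSS minus Sham on the log2 scale with the moderated standard error. Gene lists of pathways, cell types and brain regions were fixed before the data were examined: 33 lists had at least 5 measured genes, with 569 of 619 members measured, older symbols being matched through the tables. Lists were tested with camera (preset correlation of 0.01, adjusted over the 33 lists), with camera using an estimated correlation, with fry, and by a two-sided exact permutation test of the list mean per array over 70 assignments, whose smallest p is 0.0286. Region markers against the reference were set beside 10000 random lists of named genes. A gene adjusted "over the list alone" is a limma p adjusted among that list's members.

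The rule for named genes, also fixed before, took the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap, filled to 10 with the genes of smallest p in that direction, which are given as values that did not pass. It added up to 4 called members of each list, filled to 2 by p, and Fos, Arc, Egr1, Npas4, Bdnf, Fkbp5, Gfap and Ttr whatever their values. Genes outside the rule were named after their values were seen: Neurod6, Slc17a6 and Prkcd in the comparison with the reference, and Trh, Inhba, Nptx2, Gadd45b, Sik1, Ier3, Egr2, Nrn1, Vgf, Hspa1a, Hspa1b, Hspb1 and Pdyn between groups. Further genes outside the rule are named under Other observations.

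The procedure was tested on simulated data with the spread of these arrays. For ICSS against Sham over 34737 units it recovered 66.6% of units changed by 0.5 on the log2 scale, 87.8% of those changed by 0.75 and 94.8% of those changed by 1, and made 0 calls in 5 runs where no unit changed. The changed units numbered 335, 335 and 330 for these sizes over the 5 runs, many more per run than the 16 calls in the data. The adjusted threshold loosens when more units change, so these percentages overstate what the comparison itself could recover. Camera recovered 25 of 25 shifted lists and called 0 of 25 others. Units were simulated independently of each other, so these figures do not cover lists of correlated genes. The heat shock list, for example, had an estimated correlation of 0.39. Alternatives covered array scaling, a replicate block, array weights, robust moderation, single arrays left out, features as units, other thresholds and other list tests. Added after the data were seen were fits on named genes only, fits with features of 1 accession averaged first, and fits without a small block of neighbouring outlying features on Sham replicate 4. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.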

Results

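Gene expression was measured in the hippocampus of 13-week-old male Wistar rats after intracranial self-stimulation (ICSS), a procedure in which a rat works for brief trains of current delivered through an electrode aimed at the lateral hypothalamus, where stimulation is rewarding. Rats of the ICSS group self-administered 2500 trains in the session before tissue collection. Rats of the Sham group spent 40 min in the same kind of box without current. Each group had 4 pools, and each pool held hippocampi from 3 rats, taken from the side of the electrode. The labels call the pools biological replicates. RNA of each pool was labelled with Cy5 and hybridised to its own array together with a Cy3-labelled common reference made from brain tissue of both groups, so that every value is a log2 ratio of a pool to that reference. The reference cancels when ICSS is set against Sham. The 8 arrays had medians between -0.032 and 0.016 and correlated with each other at r = 0.586 to 0.873 over all features. Sham replicate 4 stood farthest from the rest, with correlations between 0.586 and 0.779. The number of arrays limits the precision of every comparison, and spot intensities were not used here, so no gene was judged as expressed or not. The time between the session and tissue collection is not given in the sources used here.

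A first comparison asked which tissue the ratios point to, because the labels describe the reference in different ways. The medians of the hippocampal marker lists lay above 0 on the Sham arrays and that of the thalamic list below it, with 6 of 7 markers of all hippocampal fields, 5 of 6 of CA1, 6 of 10 of CA2 and CA3 and 5 of 8 of dentate granule cells above 0. Neurod6, a transcription factor gene of hippocampal pyramidal neurons, had a log2 ratio of 1.69 ± 0.20 (SD, n = 4), and C1ql2, which marks dentate granule cells, reached 2.41 ± 0.25 (SD, n = 4). Slc17a6, the vesicular glutamate transporter gene of thalamic neurons, stood at -2.57 ± 0.51 (SD, n = 4), and Prkcd, another thalamic marker, at -2.73 ± 0.26 (SD, n = 4). Of 17 thalamic markers, 16 lay below 0, with a median of -0.31, lower than every one of 10000 random lists of the same size. The median was 0.76 for 7 markers of all hippocampal fields, 0.40 for 6 markers of CA1, 0.22 for 10 markers of CA2 and CA3 and 0.14 for 8 markers of dentate granule cells, at percentiles of 100, 99.99, 100 and 99.03 among random lists. On the ICSS arrays these medians were 0.48, 0.16, 0.36 and 0.33, so the order of the fields differed while the sign did not. The 13 neocortical markers had a median of -0.16, at a percentile of 0.63. Lists of pericytes, leptomeninges and fibroblasts (-0.66), interneurons (-0.36) and choroid plexus (-0.33) also lay below every random list, so low values were not particular to the thalamus. The hippocampal and thalamic values have the direction of sample over reference. The labels of the reference channel name thalamic tissue in it. The design text names hippocampal tissue alone. The thalamic values, with 16 of 17 markers below 0, argue against a reference of hippocampal tissue alone. They do not show which of the other named tissues it held or from which side.

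The comparison of ICSS with Sham addressed how self-stimulation alters hippocampal gene expression. Among named genes 6 rose and 3 fell. Nup93, which encodes a scaffold protein of the nuclear pore, was 2.01-fold higher in ICSS pools, with log2 ratios of 0.054 ± 0.028 against -0.95 ± 0.19 (SD, n = 4 each). Crem, a cAMP-responsive transcription factor gene, was 1.72-fold higher, Pla1a, a phospholipase gene, 1.69-fold, and Coq10b, which encodes a coenzyme Q binding protein of mitochondria, 1.64-fold. Fn1, the fibronectin gene, rose 1.51-fold and Kcns2, a modulatory potassium channel subunit gene, 1.42-fold. Gdf10, a growth factor gene of the TGF-beta family, fell 1.80-fold, from 1.35 ± 0.059 in Sham to 0.49 ± 0.17 in ICSS pools (SD, n = 4 each). C1ql1, which encodes a secreted synaptic organizer, fell by 0.78 on the log2 scale (SE 0.098), and Nr1d1, a repressor of the circadian clock, fell 1.52-fold. The limma adjusted p lay between 0.0134 for Nup93, Crem and Gdf10 and 0.0316 for C1ql1, and in each of the 9 genes all 4 ICSS pools lay on one side of all 4 Sham pools.

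**Figure D1:**
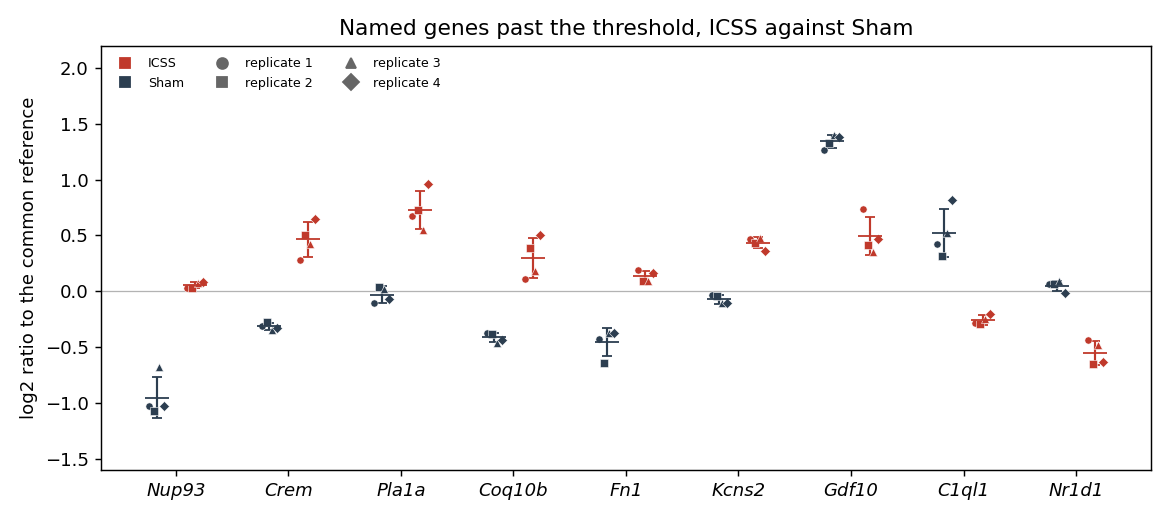
Log2 ratio to the common reference (vertical axis) of the 9 named genes past the threshold, for 4 ICSS pools and 4 Sham pools; each point is 1 array, the marker shape gives the replicate, the horizontal bar is the group mean and the error bar 1 SD. Each gene's ICSS pools lie wholly above or wholly below its Sham pools, with Sham replicate 3 apart from the other Sham pools in Nup93.

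In all, 16 of 34737 units (14870 genes and 19867 unnamed probes) passed the threshold in limma, 9 higher and 7 lower in ICSS pools, and 7 of them were unnamed probes. The call of Nup93 rested on 1 of its 2 features, which stood at -0.063 ± 0.043 in ICSS and -1.98 ± 0.29 in Sham pools (SD, n = 4 each), while the other gave 0.17 ± 0.057 and 0.077 ± 0.093. For Fn1 all 11 features were higher, by 0.49 to 0.74, and both features of Crem and of Coq10b were higher. Cryab, a small heat shock protein gene, had the largest difference among the next genes by p, 1.47 (SE 0.20, limma adjusted p = 0.0502), and its value in Sham replicate 4 was -1.66, below -0.79 to -0.69 in the other Sham pools. Recql4, a DNA helicase gene, differed by 0.51 (SE 0.070), Wfdc1 by 0.40 (SE 0.057) and Creld2, a gene of the endoplasmic reticulum stress response, by 0.43 (SE 0.062), with limma adjusted p between 0.0502 and 0.0576. On the lower side Galnt16 differed by -0.67 (SE 0.10), Ngdn by -0.38, Hp, the haptoglobin gene, by -0.50, Mtmr14 by -0.37, Ddn, the gene of the dendritic protein dendrin, by -0.38, Slc28a2, a nucleoside transporter gene, by -0.42 and Kifc3, a kinesin gene, by -0.46, and none of these 7 passed (limma adjusted p from 0.0654 to 0.0897). All ICSS pools lay on one side of all Sham pools in 2708 units, or 7.80%, where chance gives 2.86% on average. Units on the same arrays can move together, and this share was not counted for other splits of the arrays. The gap between the 2 percentages is therefore no test. The number of calls depended on single arrays: it was 153 without ICSS replicate 1, 0 without ICSS replicate 2 or 3, 6 without ICSS replicate 4, 1 without Sham replicate 1, 10 without Sham replicate 2, 1 without Sham replicate 3 and 14 without Sham replicate 4, against 4392 units at an unadjusted p below 0.05 with all arrays, and 3454 and 3312 without ICSS replicate 2 or 3. With the arrays scaled to an equal spread, 15 units were higher and 7 lower, and with quantile normalization 22 and 12.

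Of 36 immediate early genes measured, 27 had a higher mean in ICSS pools, and the mean difference was 0.22. The list had a camera adjusted p of 6.00e-06 with the preset correlation, and an adjusted p = 0.293 with an estimated correlation. Crem was the member called over all units, and 13 members, all higher, passed when adjusted over the list alone. Ptgs2, the gene of inducible cyclooxygenase, differed by 1.18 (SE 0.17, limma adjusted p = 0.0613) and Sik1, a salt-inducible kinase gene, by 0.53 (SE 0.090, limma adjusted p = 0.0897). Arc, whose product acts in synaptic plasticity, was at 1.25, 1.16 and 0.93 in ICSS replicates 2, 3 and 4 but at -0.40 in ICSS replicate 1, against -0.63 to -0.15 in the Sham pools, a difference of 1.18 (SE 0.31, limma adjusted p = 0.192). Gadd45b, a stress and DNA repair gene chosen after its values were seen, differed by 1.05 (SE 0.26), with 0.062 in ICSS replicate 1 and 1.24 to 1.49 in the other ICSS pools. The classical markers Fos, Egr1 and Npas4 differed by 0.14 (SE 0.070), -0.024 (SE 0.076) and 0.049 (SE 0.074), with limma adjusted p of 0.453, 0.918 and 0.815. Lower members included Ier3 at -0.69 (SE 0.28, limma adjusted p = 0.348) and Egr2 at -0.57 (SE 0.36, limma adjusted p = 0.544). Ier3 was at 1.31 in Sham replicate 4, above the other Sham pools.

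Late activity-regulated plasticity genes gave a mean difference of 0.43 over 21 members measured, of which 15 were higher. None was called over all units, and 12, all higher, passed when adjusted over the list alone. Bdnf, the gene of brain-derived neurotrophic factor, lay between 1.04 and 1.35 in ICSS and between 0.69 and 0.79 in Sham pools (n = 4 each), a difference of 0.46 (SE 0.069, limma adjusted p = 0.0654). Of its 12 features 11 were higher and 1 was flat, at -0.051. Rgs2, a regulator of G protein signalling, differed by 0.65 (SE 0.10, limma adjusted p = 0.0794). Inhba and Nptx2, chosen after their values were seen, differed by 1.39 and 1.03, and like Arc each lay near the Sham pools in ICSS replicate 1, at -0.15 and -0.35, while the other ICSS pools lay between 0.81 and 1.53. Timp1, a metalloproteinase inhibitor gene, differed by 1.62 (SE 0.36), again with ICSS replicate 1, at -0.64, within the Sham range. The camera adjusted p of the list was 1.64e-06 with the preset correlation, and the adjusted p = 0.293 with an estimated correlation. The neurotrophic and growth factor list, which shares Bdnf, had a mean difference of 0.12 over 24 members, 17 of them higher and 5 past the threshold when adjusted over the list alone, among them Kdr, a receptor gene of vascular endothelial growth factor, at 0.50 (SE 0.13). Its camera adjusted p was 0.0166, and its adjusted p = 0.293 with an estimated correlation.

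**Figure D2:**
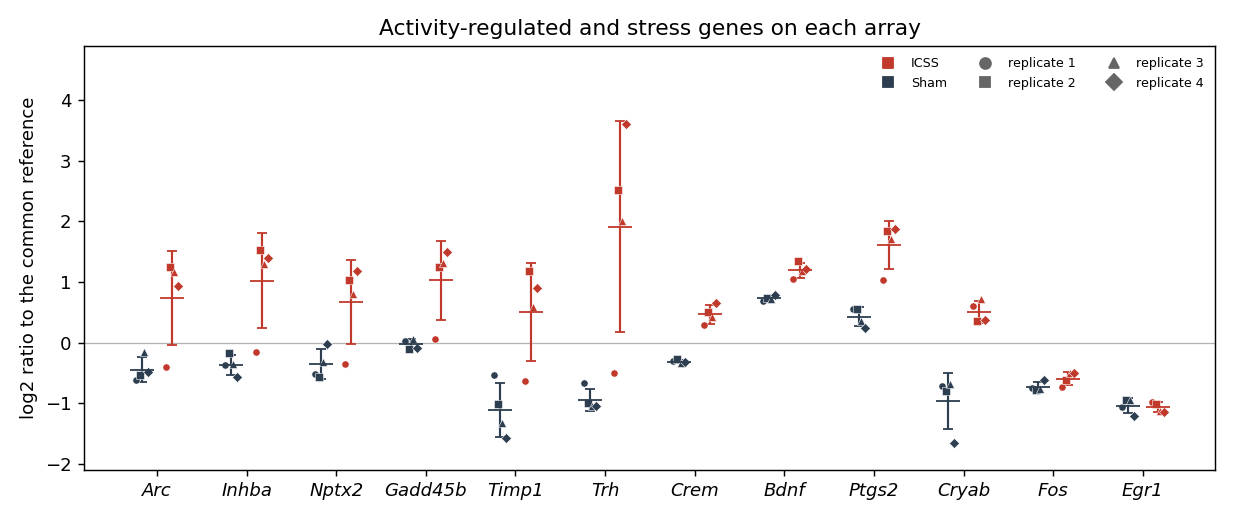
Log2 ratio to the common reference (vertical axis) of activity-regulated and stress genes for 4 ICSS pools and 4 Sham pools; each point is 1 array, the marker shape gives the replicate, the horizontal bar is the group mean and the error bar 1 SD. Arc, Inhba, Nptx2, Gadd45b, Timp1 and Trh lie near the Sham pools in ICSS replicate 1, while Crem, Bdnf, Ptgs2 and Cryab lie above all Sham pools there, and Fos and Egr1 overlap between the groups.

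All 17 heat shock and chaperone genes measured had a higher mean in ICSS pools, with a mean difference of 0.49, or 0.35 without ICSS replicate 4. None was called over all units, and 10 passed when adjusted over the list alone. Beside Cryab, Bag3, a co-chaperone gene, differed by 0.91 (SE 0.19, limma adjusted p = 0.137). Hspa1a, the inducible Hsp70 gene, differed by 1.83 (SE 0.60), with 2.70 in ICSS replicate 4 and between -0.81 and 0.20 in the other ICSS pools, and Hspb1 differed by 1.21 (SE 0.43), with 1.84 in ICSS replicate 4. Hspa1b, the close paralog of Hspa1a, differed by 0.19, and probes for these near-identical genes can pick up both. The camera adjusted p of the list was 4.92e-08 with the preset correlation, and the adjusted p = 0.293 with an estimated correlation. Glucocorticoid-induced genes had a mean difference of 0.19 over 19 members, 14 of them higher and 5 past the threshold when adjusted over the list alone. Map3k6, a stress-activated kinase gene, differed by 0.53 (SE 0.081, limma adjusted p = 0.0707), Gjb6, the connexin 30 gene, by 0.28 (SE 0.075) and Fkbp5, a co-chaperone of the glucocorticoid receptor, by 0.39 (SE 0.12, limma adjusted p = 0.253). This list had a camera adjusted p of 0.000380, and an adjusted p = 0.423 with an estimated correlation. The inflammation and acute injury list had a mean difference of 0.22 over 24 members, 21 of them higher and 3 past the threshold when adjusted over the list alone. Its array means overlapped between the groups (exact permutation p = 0.229), and the difference was 0.14 without ICSS replicate 4 and 0.13 without Sham replicate 4. Its Il1b, the interleukin 1 beta gene, differed by 0.42 (SE 0.084) and Ccl2, a chemokine gene, by 0.92 (SE 0.20), with limma adjusted p of 0.125 and 0.152. Its camera adjusted p was 0.000380, and its adjusted p = 0.441 with an estimated correlation.

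Neuropeptide genes had a mean difference of 0.30 and a median difference of 0.20 over 22 members, 16 of them higher. The list had a camera adjusted p of 0.00330, and an adjusted p = 0.293 with an estimated correlation. Adjusted over the list alone, 5 were higher and 1 was lower, and none was called over all units. Trh, the thyrotropin-releasing hormone gene, named after its values were seen, stood at 2.52, 2.01 and 3.62 in ICSS replicates 2, 3 and 4 and at -0.50 in ICSS replicate 1, against -1.05 to -0.67 in the Sham pools, a difference of 2.86 (SE 0.69, limma adjusted p = 0.162). Cartpt, the gene of the CART peptide, differed by 1.29 (SE 0.26) and Tac3, the neurokinin B gene, by 0.76 (SE 0.15), both with a limma adjusted p of 0.125. Npy, the neuropeptide Y gene, differed by 0.53 (SE 0.15). Pdyn, the prodynorphin gene, was the lower member, at 0.14 to 0.66 in ICSS and 0.80 to 1.68 in Sham pools, a difference of -0.66 (SE 0.19, limma adjusted p = 0.213).

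Lists of glutamate receptor, synaptic vesicle release and axon and cytoskeleton genes were called lower by camera with the preset correlation only, by small amounts. Of 22 glutamate receptor genes measured, 17 were lower, with a mean difference of -0.0845, and adjusted over the list alone 1 was lower and 1 higher. Gria1, an AMPA receptor subunit gene, stood at 0.79 ± 0.16 in ICSS and 1.27 ± 0.079 in Sham pools (SD, n = 4 each; limma adjusted p = 0.0949), and Grm7, a presynaptic metabotropic receptor gene, differed by 0.34 (SE 0.089). Genes of synaptic vesicle release had a mean difference of -0.090, with 17 of 21 lower. Napa, whose product acts in membrane fusion, differed by -0.22 and Slc17a7, the vesicular glutamate transporter of cortical and hippocampal neurons, by -0.20, and no member passed when adjusted over the list alone. In the axon and cytoskeleton list 18 of 28 genes were lower, with a mean difference of -0.061 and none past the threshold when adjusted over the list alone, and Ncam1 and Mapt differed by -0.235 and -0.244. The camera adjusted p of these 3 lists was 0.0308, 0.0110 and 0.0441, and the adjusted p was 0.441, 0.423 and 0.444 with an estimated correlation. Without Sham replicate 4 the mean differences shrank to -0.051, -0.050 and -0.033 and none of the 3 lists kept its call, at camera adjusted p of 0.180, 0.0853 and 0.148. The glutamate receptor list also lost it without ICSS replicate 3 (-0.068, adjusted p = 0.0859) and with quantile normalization (-0.088, adjusted p = 0.0518). The axon list lost it without ICSS replicate 1 at a larger difference (-0.074, adjusted p = 0.0595), and without ICSS replicates 3 and 4 (-0.053 for both, adjusted p = 0.0742 and 0.0755) and Sham replicate 3 (-0.049, adjusted p = 0.101). It also lost it with each array centred on its median (adjusted p = 0.0502), quantile normalization (0.0668), named genes only (0.0540) and array quality weights (0.0621).

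Other neuronal and metabolic lists were not called by camera. Postsynaptic scaffolds and kinases had a mean difference of -0.033 over 22 members (camera adjusted p = 0.130), with Shank3 and Dlg2 at -0.26 and 0.20, and 1 lower member adjusted over the list alone. Receptors of dopamine, serotonin, noradrenaline and acetylcholine had a mean difference of -0.0505 over 34 members (camera adjusted p = 0.188). Among them Htr1a, the serotonin 1A receptor gene, differed by -0.415 (SE 0.0875, limma adjusted p = 0.144), the member that passed when adjusted over the list alone, and Htr5b by -0.33. For 16 GABA genes the mean difference was -0.0049 (camera adjusted p = 0.833), with Gabra4 at 0.40, which passed when adjusted over the list alone, and Gabrd at -0.38. Memory kinase and CREB signalling genes had a mean difference of -0.027 over 18 members (camera adjusted p = 0.588), with Akt1 at -0.31 and Creb1 at 0.17. Oxidative phosphorylation had a mean difference of -0.014 over 32 members and ribosomal proteins 0.033 over 33 (camera adjusted p = 0.824 and 0.304). Their members Atp5f1a and Cycs differed by -0.24 and 0.15, and Rpl3 and Rpl23 by -0.27 and 0.175. No member of these last 3 lists passed when adjusted over the list alone. The means of these 6 lists moved by over 1.5 times when single arrays were left out, over -0.047 to -0.015 (postsynaptic), -0.076 to -0.0033 (receptors), -0.030 to 0.024 (GABA), -0.051 to 0.0043 (memory), -0.024 to -0.0047 (oxidative phosphorylation) and -0.014 to 0.071 (ribosomal).

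**Figure D3:**
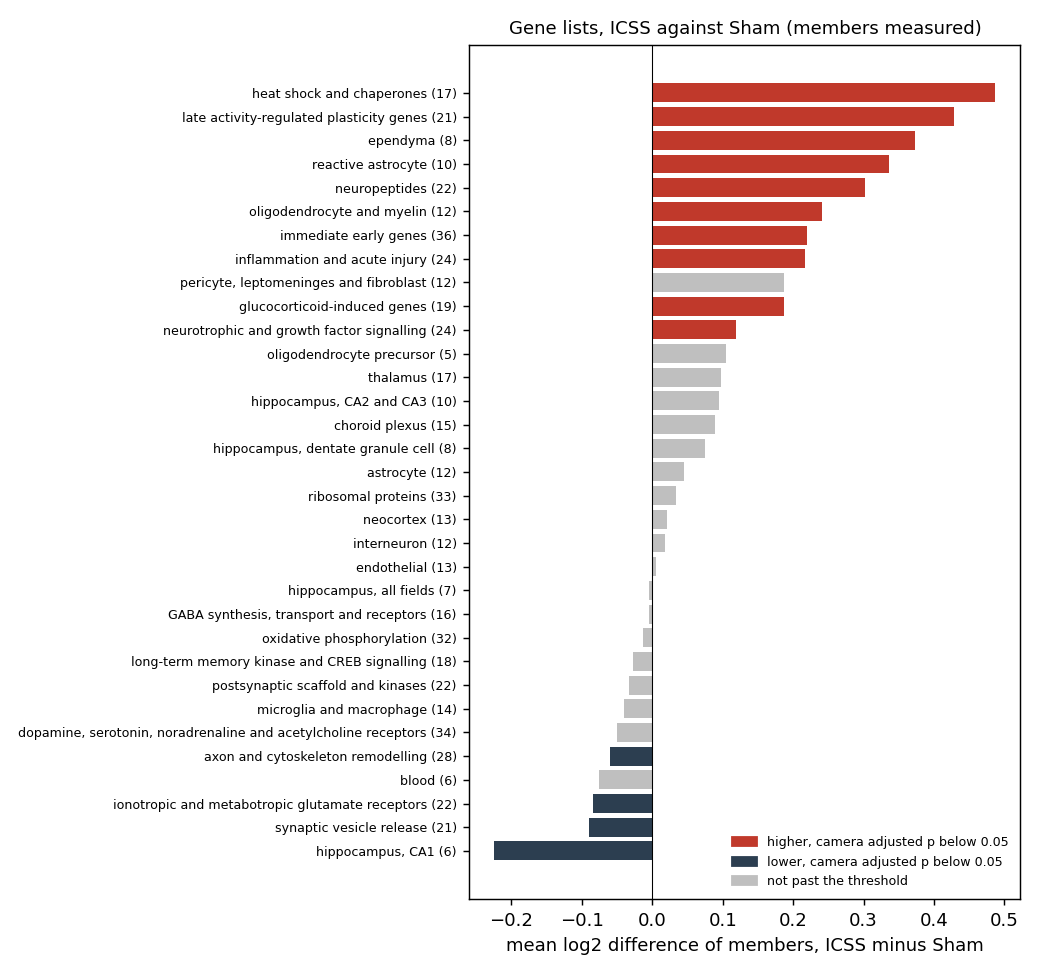
Mean log2 difference of the members of each of 33 gene lists, ICSS minus Sham (horizontal axis), with the number of members measured in brackets; red and dark bars mark lists with a camera adjusted p below 0.05 with the preset correlation, higher and lower in ICSS pools, and no list passed with an estimated correlation. Heat shock genes have the largest positive mean, 0.49, and CA1 markers the largest negative one, -0.22.

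Markers of cell types and regions were compared to see whether the makeup of the pools moved with the group. All 8 ependymal markers were higher in ICSS pools, with a list mean of 0.42 ± 0.18 against 0.042 ± 0.33 (SD, n = 4 each), and Sham replicate 4 was at -0.45 while the other Sham pools lay between 0.13 and 0.25. Without Sham replicate 4 the mean difference of the ependyma list went from 0.37 to 0.21, and camera still called it. Drc12 and Dynlrb2, genes of motile cilia, differed by 0.67 and 0.75. Of 12 myelin markers 11 were higher, with a mean difference of 0.24, and Mal and Mobp, genes of myelin proteins, were at -1.08 and -1.03 in Sham replicate 4, below all other pools. Without Sham replicate 4 the myelin list lost its call (mean difference 0.060, camera adjusted p = 0.461), and also without ICSS replicate 1 (0.20, 0.0727) or 3 (0.14, 0.240) and with array quality weights (0.18, 0.0621). Reactive astrocyte markers had a mean difference of 0.34, with Timp1 and Cxcl10 at 1.62 and 0.36, and their call was lost without ICSS replicate 4 (0.27, camera adjusted p = 0.111) or Sham replicate 4 (0.25, 0.0992), while Gfap, the gene of the astrocyte filament protein, differed by 0.345 (SE 0.21, limma adjusted p = 0.527). All 6 CA1 markers were lower, with a mean difference of -0.22, among them Fibcd1 at -0.31 and Pou3f1 at -0.38. Camera gave adjusted p of 0.00542 for ependyma, 0.0234 for myelin, 0.0181 for reactive astrocytes and 0.00664 for CA1, and with an estimated correlation the adjusted p was 0.423, 0.694, 0.441 and 0.293. Adjusted over the list alone, 1 reactive astrocyte marker, Timp1, passed and no marker of the other 3 lists did.

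No other marker list was called by camera. Dentate granule cell markers had a mean difference of 0.075 (camera adjusted p = 0.0593), with 7 of 8 members higher: C1ql2, the lower one, differed by -0.58 (SE 0.11) and Pdzd2 by 0.48 (SE 0.12), and adjusted over the list alone 2 were higher and 1 lower. The mean differences were 0.19 for pericytes, leptomeninges and fibroblasts, 0.098 for thalamus, 0.094 for CA2 and CA3 and 0.10 for oligodendrocyte precursors (camera adjusted p = 0.0622, 0.0675, 0.0822 and 0.158), with Aldh1a2 and Ogn at 0.32 and 0.46, Shox2 and Zic1 at 0.35 and 0.27, Pcp4 and Amigo2 at 0.25 and 0.15, and Pdgfra and Olig1 at 0.14 and 0.21. Without ICSS replicate 3 the means were 0.075 for pericytes, 0.033 for thalamus and 0.055 for precursors, and without Sham replicate 4 that of CA2 and CA3 was 0.053. Blood markers differed by -0.076 and microglia by -0.040 (camera adjusted p = 0.443 for both), with Hbb and Hbb-b1 at -0.30 and -0.19 and Tmem119 and Trem2 at -0.17 and -0.46. Trem2 was at 1.11 in Sham replicate 1 and between -0.63 and 0.11 in the other Sham pools. Markers of all hippocampal fields, astrocytes, endothelium, neocortex, choroid plexus and interneurons had mean differences of -0.0043, 0.046, 0.0059, 0.020, 0.089 and 0.017, with camera adjusted p of 0.661, 0.737, 0.761, 0.761, 0.961 and 0.961. Here Zbtb20 and Neurod2 were at -0.28 and 0.37, Slc1a3 and Aqp4 at -0.21 and 0.28, Itm2a and Slco1c1 at -0.31 and -0.16, Egr3 and Myl4 at 0.34 and 0.14, Tmem72 and Kl at -0.31 and 0.21, and Gad2 at 0.26. Some of these leaned on 1 Sham pool. Tmem72 was at 0.87 in Sham replicate 2, against 0.0012 to 0.17 in the other Sham pools. Kl was at 0.34 in Sham replicate 1, against -0.59 to -0.48, and Neurod2 at 0.80 in Sham replicate 4, against 1.45 to 1.61. Ttr, the transthyretin gene of the choroid plexus, ranged from -1.24 to 0.31 in ICSS pools and from -2.41 to 1.03 in Sham pools. The choroid plexus mean went from -0.11 without Sham replicate 4 to 0.49 without Sham replicate 1. With single arrays left out the means also ranged over -0.16 to 0.14 for microglia, -0.12 to -0.036 for blood, -0.053 to 0.031 for all fields, 0.014 to 0.066 for astrocytes, -0.013 to 0.022 for endothelium, 0.0042 to 0.053 for neocortex and -0.0365 to 0.11 for interneurons. None of the lists in this paragraph other than the dentate one had a member past the threshold when adjusted over the list alone.

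Of the 33 lists, 14 were called by camera with the preset correlation, 10 higher and 4 lower, and 0 with an estimated correlation, where 3 had an unadjusted p below 0.05. The count was 9 without Sham replicate 4. Fry, which tests whether a list's genes move one way on balance, called 2 lists, immediate early genes and neurotrophic factors (adjusted p = 0.0304 for both). For changes in either direction fry called 9 lists. These were heat shock, late plasticity, immediate early, glucocorticoid, neuropeptide, neurotrophic factor, glutamate receptor, dentate granule cell and endothelial genes. The dentate list had the smallest adjusted p in that form of fry, 9.65e-05, and the endothelial list had 0.0066. In a two-sided exact permutation test of the list means over 70 assignments of the arrays, 6 lists reached the smallest possible p, 0.0286: heat shock, late plasticity, immediate early, glucocorticoid, neuropeptide and ependyma. None passed after adjustment over the 33 lists (adjusted p = 0.157). The exact test gave 6 lists with all arrays, 5, 6, 5 and 4 without ICSS replicates 1, 2, 3 and 4, and 3, 1, 1 and 1 without Sham replicates 1, 2, 3 and 4. Leaving out an array cannot undo the separation of a list whose ICSS means all lie above its Sham means. It makes the groups unequal, however, and a separated list then need not reach the smallest possible p. The counts without an array are therefore not comparable with the 6 from all arrays.

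**Figure D4:**
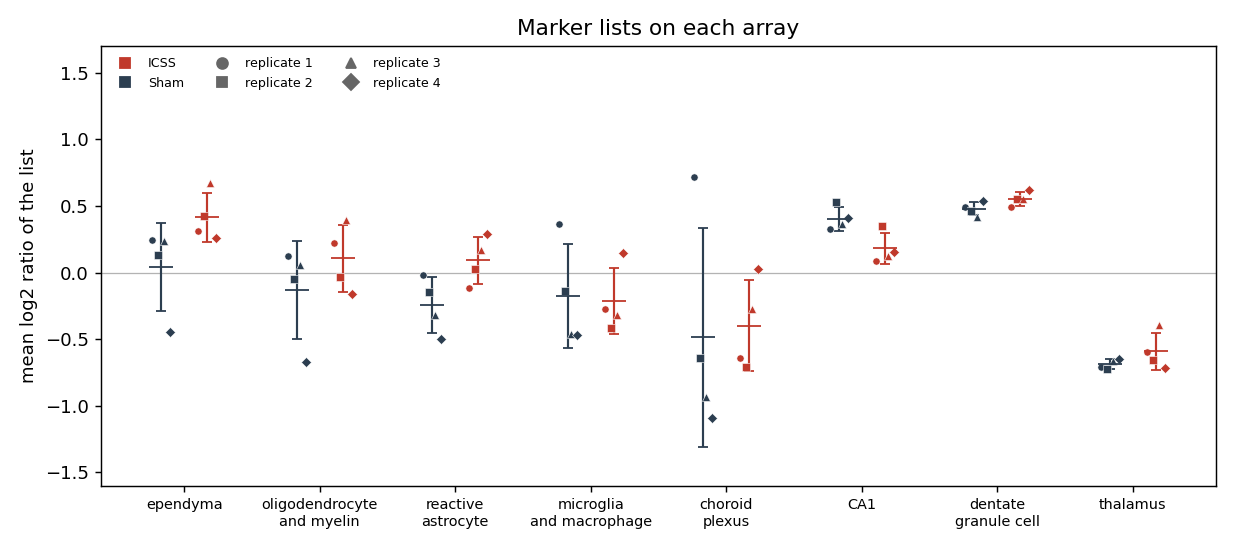
Mean log2 ratio of the members of 8 marker lists (vertical axis) for 4 ICSS pools and 4 Sham pools; each point is 1 array, the marker shape gives the replicate, the horizontal bar is the group mean and the error bar 1 SD. Sham replicate 4 is the lowest pool for ependyma, myelin, reactive astrocyte and choroid plexus markers, and choroid plexus and microglia markers spread widely within both groups.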

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

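Of the tests in this part, those on chance, on other tissue, on 1 unusual array, on a Sham pool under an ICSS label, on the spread of the share and on a local defect were chosen after the results were seen, and those on normalization and on compressed ratios before. In 242 groups of 4 arrays checked, 18 had 1 array far from the other 3, measured as its gap to the nearest of the others over the group's range, where chance gives about 1 in 20, or 12.1. Genes named after their values were seen were among those checked, and Inhba, Vgf, Nrn1 and Trh are among the 18. The 18 therefore cannot be weighed fairly against 12.1. In ICSS replicate 1 the ratio was 0.858 for Inhba (-0.15 against 1.29 to 1.53), 0.856 for Vgf (-0.60 against -0.17 to -0.093) and 0.953 for the array median (0.016 against -0.023 to -0.021). In Sham replicate 4 it was 0.890 for Cryab (-1.66 against -0.79 to -0.69), 0.945 for Nrn1 (-0.32 against 0.35 to 0.39), 0.916 for Mobp (-1.03 against -0.22 to -0.15), 0.835 for the ependymal list mean (-0.45 against 0.13 to 0.25) and 0.880 for the array median (-0.032 against -0.024 to -0.022). In ICSS replicate 4 it was 0.927 for Map3k6 (-0.66 against -0.99 to -0.96), 0.852 for Slc17a7 (0.77 against 0.48 to 0.52), 0.925 for Trem2 (0.59 against -0.60 to -0.51) and 0.877 for Itm2a (-0.58 against -0.33 to -0.29). In Sham replicate 1 it was 0.835 for Gjb6 (-0.59 against -0.40 to -0.36), 0.850 for Aldh1a2 (-0.64 against -0.51 to -0.49), 0.877 for Kl (0.34 against -0.59 to -0.48) and 0.868 for Trh (-0.67 against -1.054 to -1.004). Sham replicate 3 stood apart for Nup93 with 0.883 (-0.68 against -1.08 to -1.03), and ICSS replicate 2 for Kifc3 with 0.865 (-0.75 against -0.63 to -0.61).

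The 16 calls between ICSS and Sham exceeded those of every other grouping: 1 of the 35 splits of the 8 arrays gave as many, the real one, and the highest other gave 1 call. This argues against chance for that count but cannot exclude it, since 1 in 35 is the smallest share the test can give. For the 14 lists chance stays open, because 4 of the 35 splits gave as many and the highest other gave 20.

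The immediate early, late plasticity and heat shock lists had higher means in ICSS pools, with 27 of 36, 15 of 21 and 17 of 17 members higher and a camera adjusted p = 0.293 with an estimated correlation for each. Quantile normalization left at least 96.4% of each list's mean difference, which argues against a scaling difference left in the deposited ratios. Those ratios were already alike in spread, with interquartile ranges of 0.2545 to 0.2627, and scaling before deposit was not tested. All 4 ICSS arrays lay above every Sham array in each list. This count replaced the percent left without any 1 array (at least 72.6%) after both were seen. The exact permutation p of 0.0286 of each list already implied that count, so it is no separate test of 1 unusual array. A different tissue makeup of the ICSS pools stays open. With the dentate granule cell score as a covariate 68.0% and 64.4% of the immediate early and late plasticity differences were left. With the reactive astrocyte score 53.7% of the heat shock difference was left. Each percentage lay within 1 standard error of a 50% bound. Each was also the lowest over the marker scores, and the plain astrocyte score left 83.3% of the heat shock difference. The reactive astrocyte list holds Timp1, also a late plasticity gene, and in the dentate list C1ql2 and Pdzd2 moved in opposite directions. These scores therefore cannot measure makeup apart from a response. The 50% bound was first applied without the error, by which the makeup explanation would have been set aside, and the stricter form was chosen after the result was seen. A response of hippocampal cells to stimulation may account for the pattern, but with these tests it cannot be told apart from a shift in makeup, because the standard errors of these percentages, 29.0, 26.9 and 34.8, span the bound.

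ICSS replicate 1 lay near the Sham pools for Arc, Inhba, Nptx2, Trh and Timp1 but with the other ICSS pools for Crem, Bdnf and Cryab. Compressed ratios on that array are argued against by a slope of 0.889 on the other ICSS arrays over all named genes, while over the 150 units of smallest p without this array it kept a median share of 0.355 of the ICSS difference. Whether it could be a Sham pool under an ICSS label cannot be told, because Sham replicate 1, left out in the same way, had a share of 0.331 and the other Sham arrays 0.245, 0.104 and -0.053, against 0.879 to 0.940 for the other ICSS arrays. Whether the pool responded less as a whole cannot be told either, because the interquartile range of its share between units, 0.490, lay within 0.403 to 0.760 for the other ICSS arrays and also within 0.376 to 0.631 for left-out Sham arrays, a comparison added after the result was seen.

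Sham replicate 4 had extreme values at single features. Of its 36 features that deviated by over 2 from the median of the other arrays, neighbours in the array grid formed 16 pairs, where 1000 random placements gave at most 2, and the other arrays had 0 or 1 pair. A local defect on the array is a candidate explanation for the 72 features in that block, 16 of which deviated by over 2. With the block left out camera again called 14 lists. The cause of the low ependymal and myelin markers of this pool was not tested.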

How the results depend on the processing

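The fits on named genes, on averaged accessions and without the defect block of Sham replicate 4 were chosen after seeing the data. The 16 calls (9 higher, 7 lower) became 34 (22 higher, 12 lower) with quantile normalization, 22 (15 higher) with scaling to equal spread, 34 (25 higher) with array quality weights, 22 (15 higher) with robust eBayes, 22 (15 higher) with features of 1 accession averaged first and 22 (15 higher) without the defect block, and all 16 were among the calls in each of these. Named genes alone gave 13 (3 lower, 9 shared), features as units 53 (45 higher), an adjusted p below 0.10 gave 90 (53 higher, 37 lower) and an unadjusted p below 0.01 gave 1391 (700 higher, 691 lower). Leaving out single arrays gave 0 to 153 calls (0 to 121 higher, 0 to 32 lower). The unmoderated equal-variance test called 0 units, with 3998 at an unadjusted p below 0.05. The replicate block called 0 (0 higher, 0 lower), with 4544 at an unadjusted p below 0.05, and 13 lists, the axon list losing its call (adjusted p = 0.0594). Same-numbered arrays correlated at -0.053, 0.058, 0.043 and 0.047 after removal of group means. No ICSS array correlated best with its own number. These values show no pairing by number, but 4 correlations near 0 cannot exclude one. Lists called were 0 by camera with an estimated correlation, 2 by fry in 1 direction, 9 by fry in either direction, and 9 to 18 when single arrays were left out. The exact test gave 1 to 6 lists, with unequal groups where an array was left out. ICSS arrays in place of Sham arrays moved the region medians to 0.33 (dentate), 0.16 (CA1), 0.36 (CA2 and CA3) and 0.48 (all fields), with the same sign. Signs turned for 1 feature each of Bdnf (-0.051), Ccl2 (-0.061) and Akt1 (0.058) and for 2 of 10 features of Egr1 (up to 0.059). Without single arrays Egr1 ranged from -0.082 to 0.0082 (0.0029 without ICSS replicate 4, 0.0082 and 0.0080 without Sham replicates 2 and 3) and Ttr from -0.12 to 1.03 (-0.022 without ICSS replicate 4, -0.12 without Sham replicate 4). The cause of these moves was not tested. The 9 called genes kept their direction in all 17 refits but their call in only 9 (Coq10b) to 13 (Nup93), with a highest adjusted p between 0.0902 (Crem, Nup93) and 0.152 (C1ql1, Coq10b). No filter row could be made, since no value was missing, and robust eBayes has no camera form. Signal over background was not used here.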

Other observations

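In limma 46 named genes had an adjusted p below 0.10, 30 higher and 16 lower, the 9 genes past 0.05 included. Several of those between 0.05 and 0.10 were named here after their values were seen. Among the higher ones were Manf, a gene of the endoplasmic reticulum stress response like Creld2, at 0.34 (SE 0.062), Adm, the adrenomedullin gene, at 0.70 (SE 0.12), P4ha1, a collagen prolyl hydroxylase gene, at 0.49 (SE 0.075), Pdp1, a phosphatase gene of the pyruvate dehydrogenase complex, at 0.79 (SE 0.13), and Kcnh1, a potassium channel gene, at 0.50 (SE 0.083). Adora2a, an adenosine receptor gene of the striatum, was higher by 0.31 (SE 0.052) at a level far below the reference, -2.03 ± 0.051 against -2.33 ± 0.034 (SD, n = 4 each). Among the lower ones were Hdac10 at -0.47 (SE 0.080) and Gpc3, a glypican gene, at -0.45 (SE 0.079).

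The named genes with the lowest ratios in Sham pools were of several kinds. Genes in this paragraph were named after their values were seen. Pmch, the melanin-concentrating hormone gene of the lateral hypothalamus, had the lowest named value in Sham pools, -6.11 ± 0.14 (SD, n = 4), followed by Cyp11b1, a steroid hydroxylase gene, at -3.39 ± 0.41 and Srpk3, a kinase gene, at -2.81 ± 0.69. Tac1 stood at -2.76 ± 0.27 and Rgs9, a gene of striatal neurons, at -2.20 ± 0.29. Choroid plexus genes varied by pool in both groups: Sostdc1 ranged from -4.05 in Sham replicate 4 to 2.16 in Sham replicate 1, with 0.35 in ICSS replicate 4. Spp1, the osteopontin gene, was at 0.38 in Sham replicate 1 and 0.068 in ICSS replicate 4, and between -3.76 and -2.30 in the other pools.

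The fall of Nr1d1 raised the question, written before the values of the clock genes listed for it were looked at, whether the ICSS pools may have been taken at another time of day. Of 8 clock output and repressor genes listed 5 were measured and 4 were lower, with a median difference of -0.24. Per1, a member of the immediate early list and not of that one, differed by -0.18 (SE 0.065). Dbp, at -0.36 (SE 0.10), and Tef, at -0.24 (SE 0.058), were lower in all 4 ICSS pools than in all 4 Sham pools, and Per2 differed by -0.27 (SE 0.15), but Nr1d2 and Per3 differed by -0.019 and 0.00010. Of 4 genes of the opposite phase 2 were higher, with Npas2 at -0.32 and Cry1 at 0.16. The 6 lower genes of 8 set for the decision could not be reached with the genes measured, and none of these had a limma adjusted p below 0.16, so another time of day remains open.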
